A study of Mus musculus with 4 samples.

How the data were processed

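The data are RNA sequencing profiles of primary satellite cells of mouse extensor digitorum longus muscle, in 2 Control and 2 ERβ scKO libraries; the series text speaks of triplicates, but 2 libraries per group were deposited. Libraries were made from polyadenylated RNA with a stranded kit, per the labels' protocols. Reads were processed by the authors with TopHat and Cufflinks on mm10, per the submitters' processing notes, which give no versions and no annotation. The deposited gene table holds an FPKM value per gene and library, computed by the authors, and their group means, which equal the mean of the library values to within 0.007. It also holds the authors' log2 fold change of ERβ scKO over Control, their test statistic, and a p-value and q-value per gene from the authors' own test, whose column names are those of a Cuffdiff gene table. The authors' q equals a Benjamini-Hochberg adjustment of their p over the 9426 rows marked as tested to within 0.0001. A further 13772 rows were marked as not tested and 153 as having too little data. Of the symbols, 27 had been turned into dates, 2 of them repeated; these stayed in the tests and are not named. A second deposited sheet repeats 306 rows of the gene table.

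The planned comparison took the table to hold group values; since it holds library values, the per-library comparison planned for that case was run as well. FPKM values are not counts, so no count test was run. Library values were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend in the variance, over 11201 genes with a mean of at least 1 FPKM over all libraries, at a Benjamini-Hochberg adjusted p of 0.05. Log2 ratios of group means use the same pseudocount of 1. No scaling was applied beyond the authors' own; upper quartile scaling would multiply ERβ scKO values by 1.014 and moves the median log2 ratio of all genes from −0.005 to 0.014.

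Before the data were examined, 38 gene lists, the rule for named genes, the tests and a first set of alternatives were fixed. For each list with at least 5 measured genes the median log2 ratio was placed among those of 10000 random lists of the same size, matched on mean expression in 20 bins; this describes these libraries and is not a p-value. Lists under the 2.5 or over the 97.5 percentile are described in the results. The authors' p and limma's p were also adjusted over each list alone. Set tests over 31 lists were added after the data were seen. Limma's camera compares a list with other genes, with a preset correlation of 0.01 or an estimated one. Fry tests whether a list's genes move one way on balance without comparing them with other genes. With an estimated correlation camera's p rests on the few residual degrees of freedom of 4 libraries, which leaves it little power. Circadian clock genes, at an estimated correlation of −0.046, below the preset, went from an unadjusted camera p of 0.0157 to 0.126. A call lost with an estimated correlation can therefore not be put down to correlation between genes from its loss alone. Where the estimate is far above the preset, correlation could also end a call. In the lists outside the percentile limits camera's direction had the sign of the median; among lists with medians near 0 it differed for Notch and quiescence, TGF-beta and BMP, Wnt, integrins and adhesion, fibroblast and Schwann markers. The rule names the genes with the largest ratios among those with the authors' q under 0.05, of which there were none, 2 to 4 members of each list outside the limits, and 9 fixed genes, which gave 28 genes. Other genes named were chosen after their values were seen, and are said to be so.

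The files give no read counts. In FPKM a gene's values move in steps that depend on its length, and among 1328 genes with a single annotated transcript longer than 1500 bases the step gave estimates of 2500000, 3000000, 2800000 and 2900000 fragments (bootstrap ranges 2500000 to 2600000, 2900000 to 3000000, 2700000 to 2800000 and 2900000 to 3000000) for Control replicates 1 and 2 and ERβ scKO replicates 1 and 2. Limits of 3 fragments were taken from these estimates and cover counting error only. They are not used for very short genes, where the length the authors divided by is not in the files. Transcript lengths, GC content and sequences came from GENCODE M21 on the same build, which matched 92.6% of the symbols and gave the GC content of 93.9% of the measured genes; 10495 genes of at least 300 bases entered the GC analysis, in which a loess curve (span 0.5) of each library's deviation on GC content was subtracted.

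The alternatives were other q and p thresholds, the authors' p adjusted again over expressed genes, pseudocounts of 0.1 and 5, a mean of at least 5 FPKM or no filter, centring or upper quartile scaling, 10 expression bins, list means, lists without their most changed gene, each library left out in turn, replicate number as a block, the libraries of each replicate number alone, short genes left out and the GC trend removed. Where 1 library of a group was left, limma's spread came from the other group, so that the lone library is assumed to vary like them. The procedures were tested on simulated data: of 50 genes each changed 1.5-, 2-, 4- and 8-fold among 11201, limma recovered 0%, 26%, 62% and 78%, with 2 false calls; camera found a list of 40 genes shifted by 0.3 and called 7 of 100 unchanged lists at an unadjusted p of 0.05; and 9 of 200 unchanged lists fell outside the percentile limits. In these simulations genes varied independently and the unchanged lists were random genes. They do not show how often a list whose members move together would be called or fall outside. Camera estimated correlations of 0.051 for cell cycle, 0.03 for cholesterol synthesis, 0.508 for collagen and 0.623 for sarcomere genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6 was used for the remaining steps and matplotlib 3.10.9 for figures.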

Results

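Polyadenylated RNA was sequenced from primary satellite cells, the stem cells of skeletal muscle, obtained from the extensor digitorum longus muscle of C57BL/6 mice aged 6 to 8 weeks. The series compares cells of Control mice with cells of mice that lack estrogen receptor β in satellite cells (ERβ scKO), and by its title concerns the receptor's part in the muscle mass of young females and in how their muscle stem cells multiply. There were 2 libraries per group, 4 in all. The deposited gene table held 23351 rows on mm10, and 11201 of them had a mean of at least 1 FPKM (fragments per kilobase of transcript, scaled to sequencing depth) over the 4 libraries. From the spacing of low values the libraries held about 2500000 and 3000000 fragments in Control replicates 1 and 2, and about 2800000 and 2900000 in ERβ scKO replicates 1 and 2. Genes at 1 FPKM or more numbered 11123 and 11108 in the Control libraries and 11191 and 11188 in the ERβ scKO libraries. Values are given below as group mean ± SD with n = 2 libraries per group, log2 ratios are of ERβ scKO over Control on the log2(FPKM + 1) scale, which understates changes of low genes, and coordinates are mm10.

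The first question was how the transcripts of ERβ scKO cells differed from those of Control cells in groups of genes fixed before the data were examined. Genes of the cell cycle were lower in ERβ scKO: 41 of the 45 measured had a lower mean, with a list median of −0.26. None of 10000 random lists of similarly expressed genes had a median as low. In 29 of the 45 genes (64.4%) both ERβ scKO libraries were below both Control libraries, against 18.3% of all measured genes and 16.7% by chance. Cdca8, a subunit of the chromosomal passenger complex that acts in mitosis (chromosome 4, 124918465 to 124936917), was at 49.8 ± 0.236 FPKM in Control and 33.4 ± 0.0801 in ERβ scKO. Mcm2, part of the helicase that opens DNA for replication (chromosome 6, 88883474 to 88898780), was at 43.1 ± 7.91 FPKM in Control and 28.9 ± 3.05 in ERβ scKO. Bub1b, Plk1 and Mcm5 had log2 ratios of −0.41, −0.44 and −0.44. These 5 genes were the list members with the authors' p under 0.05, all lower in ERβ scKO, and they were chosen after their values were seen. The 3 members named by a rule fixed in advance differed by less: Rrm2, a subunit of ribonucleotide reductase, had a log2 ratio of −0.10, Pcna, the clamp of DNA polymerase, −0.13, and the proliferation marker Mki67 −0.07, with 33.5 ± 12.7 FPKM in Control and 31.8 ± 1.01 in ERβ scKO. No cell cycle gene passed the authors' q threshold of 0.05 or limma's over all genes, and none passed when adjusted over the list alone. As a set, the list was lower by limma's camera test with a preset correlation between genes (adjusted p = 2.47e-08 over 31 lists), and with replicate number as a block (adjusted p = 8.57e-08). The call was lost with an estimated correlation (adjusted p = 0.872 with an estimated correlation), and fry gave adjusted p = 0.343. With 4 libraries the estimated form has little power. The loss does not by itself show that correlation between genes explains the call. The estimated correlation was 0.051 for this list and 0.03 for cholesterol synthesis below. For collagens and sarcomere genes below it was 0.508 and 0.623, far above the preset 0.01, and correlation of that size could end their calls. The median was −0.22 between the replicate 1 libraries and −0.28 between the replicate 2 libraries, while Control replicate 2 differed from Control replicate 1 by −0.02. Malat1 and Neat1, nuclear RNAs whose level can vary with RNA quality, were higher in both ERβ scKO libraries than in either Control library, with log2 ratios of 0.78 and 0.67. With 2 libraries per group there are 3 splits of the 4 libraries, too few for a permutation test to reach 0.05.

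**Figure D1:**
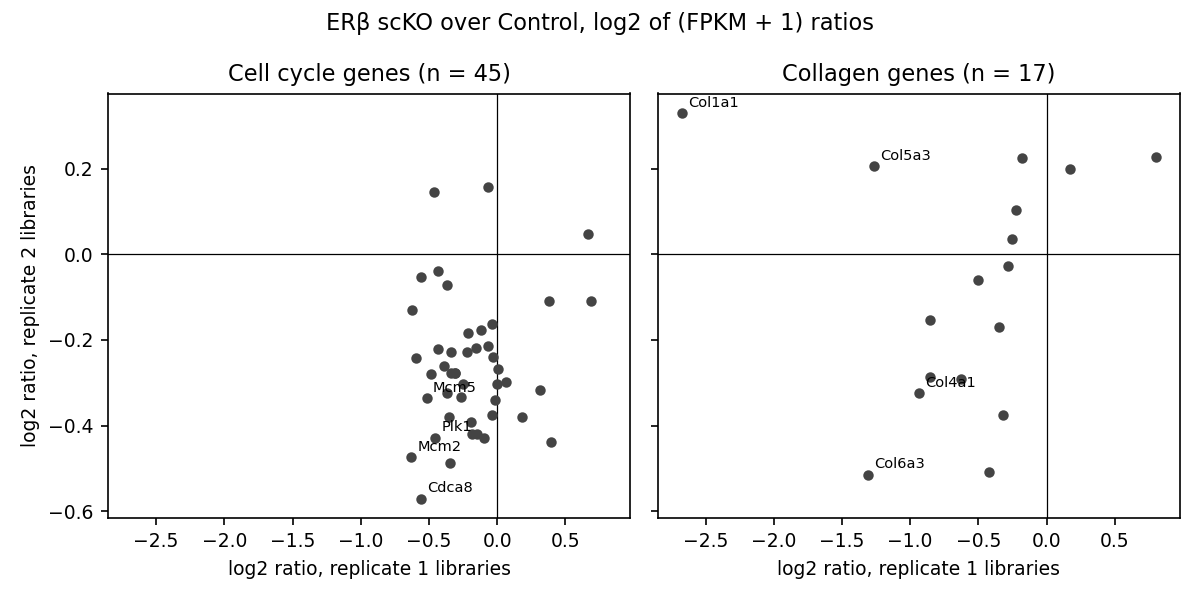
Each point is 1 gene, with its log2 ratio of ERβ scKO over Control between the replicate 1 libraries on the horizontal axis and between the replicate 2 libraries on the vertical axis, on the FPKM + 1 scale. Of 45 cell cycle genes (left), 34 were lower in both pairs and 1 was higher in both; of 17 collagen genes (right), 10 were lower in both and 2 higher in both, and the largest differences were between the replicate 1 libraries.

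Genes of cholesterol and fatty acid synthesis were lower in ERβ scKO as well, with 21 of 22 measured genes lower and a list median of −0.22. No random list had a median as low. Both ERβ scKO libraries were below both Control libraries in 13 of the 22 (59.1%, against 18.3% of all measured genes and 16.7% by chance). Scd2, a stearoyl-CoA desaturase (chromosome 19), was at 67.2 ± 4.31 FPKM in Control and 54.0 ± 0.598 in ERβ scKO, and Fdps, which makes farnesyl diphosphate (chromosome 3), was at 63.7 ± 2.79 and 53.5 ± 4.67 FPKM. Srebf2, the main transcription factor of cholesterol synthesis genes, and Fasn, the fatty acid synthase, had log2 ratios of −0.41 and −0.42; these 2 had the authors' p under 0.05 and were chosen after their values were seen. None of the 22 passed the authors' q or limma's adjusted p, over all genes or adjusted over the list alone. The camera test called the list lower (adjusted p = 3.06e-05, and 5.24e-05 with replicate number as a block), and the call was lost with an estimated correlation (adjusted p = 0.872 with an estimated correlation). The median was −0.13 between the replicate 1 libraries, where its percentile among random lists was 6.38, and −0.29 between the replicate 2 libraries. The same libraries had the higher values of Malat1 and Neat1 (log2 ratios 0.78 and 0.67).

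Collagen genes were lower in ERβ scKO on average, with 15 of 17 measured genes lower and a list median of −0.40, but the difference rested on Control replicate 1. Without that library the median was 0.06, and between the replicate 2 libraries it was −0.06, with 10 of 17 lower. Without ERβ scKO replicate 2 it was −0.24. Both ERβ scKO libraries were below both Control libraries in 6 of the 17 (35.3%, against 18.3% of all measured genes and 16.7% by chance). Col1a1, a chain of fibrillar type I collagen (chromosome 11, 94936270 to 94951856), was at 18.8 FPKM in Control replicate 1 and 0.909 in Control replicate 2, against 2.09 and 1.40 in the ERβ scKO libraries. Col6a3, a chain of type VI collagen (chromosome 1, 90766860 to 90843971), was at 18.1 and 1.81 FPKM in Control and at 6.71 and 0.966 in ERβ scKO. The 2 collagens named by the rule had log2 ratios of −0.16 (Col5a2) and 0.00 (Col18a1). Adjusted over the list alone, the authors' p called 8 of the 13 collagens they tested: Col1a1, Col1a2, Col4a1, Col4a2, Col5a1, Col6a3 and Col12a1 lower and Col25a1 higher in ERβ scKO. The collagens other than Col5a2 and Col18a1 were chosen after their values were seen. Over all genes their q called 0, and limma called 0 over all genes and over the list alone. The camera test gave adjusted p = 0.0307, which became 0.975 as an adjusted p with an estimated correlation, 0.0022 with replicate number as a block and 0.887, in the opposite direction, without Control replicate 1; without ERβ scKO replicate 2 it was 0.28. Malat1 and Neat1 were higher in the same ERβ scKO libraries (log2 ratios 0.78 and 0.67).

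The medians of 3 related groups also changed sign without Control replicate 1. Non-collagen matrix proteins had a median of −0.12 (22 of 33 lower), matrix remodelling genes −0.12 (15 of 26 lower) and targets of YAP and TAZ, transcription regulators that respond to cell tension, −0.16 (11 of 16 lower). Without Control replicate 1 these medians were 0.14, 0.18 and 0.05. Between the replicate 2 libraries they were 0.04, 0.10 and 0.07. Without ERβ scKO replicate 2 the medians of the first and second of these lists were −0.06 and −0.06, and without Control replicate 2 the 3 medians were −0.24, −0.33 and −0.28. Without ERβ scKO replicate 1 the remodelling median was −0.23. With each library's trend with GC content removed the medians were −0.10, 0.01 and −0.06, the last 2 within the range of their random lists. Members named by the rule went both ways: Spp1 (osteopontin) had a log2 ratio of 0.39 and Sparc −0.12, Timp1 −0.06 and Serpinh1, a collagen chaperone, −0.32, and Ankrd1 0.33 and Axl −0.18. Ctgf, which encodes a secreted matrix-associated protein, was at 180 and 29.8 FPKM in Control and 89.2 and 31.4 in ERβ scKO, and was chosen after its values were seen. Camera called none of these 3 lists (adjusted p = 0.55, 0.927 and 0.69 in the order above).

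Genes of the sarcomere were higher in ERβ scKO on average, with 34 of 38 measured genes higher and a list median of 0.25, above the medians of all 10000 random lists. Both ERβ scKO libraries were above both Control libraries in 11 of the 38 (28.9%, against 18.3% of all measured genes and 16.7% by chance), and below both in 1. Tpm1 (tropomyosin) had a log2 ratio of 0.05 and Mylpf, a fast myosin light chain, 0.34, with 1730 ± 560 FPKM in Control and 2189 ± 297 in ERβ scKO. The authors' p was under 0.05 for 8 members, all higher in ERβ scKO: Myh1, Myl1, Tnnc2, Ttn, Casq1, Casq2, Myom2 and Pgam2, chosen after their values were seen. Their q and limma called 0, and adjusted over the list alone 0 were called from either. Camera called the list higher (adjusted p = 3.06e-05, and 3.44e-07 with replicate number as a block), and the call was lost with an estimated correlation (adjusted p = 0.975 with an estimated correlation). The median was 0.04 without Control replicate 1, 0.56 without Control replicate 2, 0.38 without ERβ scKO replicate 1 and 0.15 without ERβ scKO replicate 2. The nuclear RNAs Malat1 and Neat1 were also higher in both ERβ scKO libraries (log2 ratios 0.78 and 0.67). The camera adjusted p was 0.7 without Control replicate 1 and 0.154 without ERβ scKO replicate 2. Between the replicate 1 libraries the median was 0.47 and between the replicate 2 libraries 0.15. Genes of myogenic commitment and fusion had a median of 0.16 (14 of 20 higher), which was 0.05, 0.34, 0.25 and 0.08 with Control replicate 1, Control replicate 2, ERβ scKO replicate 1 and ERβ scKO replicate 2 left out in turn; it was 0.23 between the replicate 1 libraries and 0.10 between the replicate 2 libraries, and camera did not call it (adjusted p = 0.162). Myog (myogenin) was at 558 ± 90.1 FPKM in Control and 641 ± 26.6 in ERβ scKO, and Myh3, the embryonic myosin heavy chain, at 339 ± 122 and 408 ± 72.2.

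**Figure D2:**
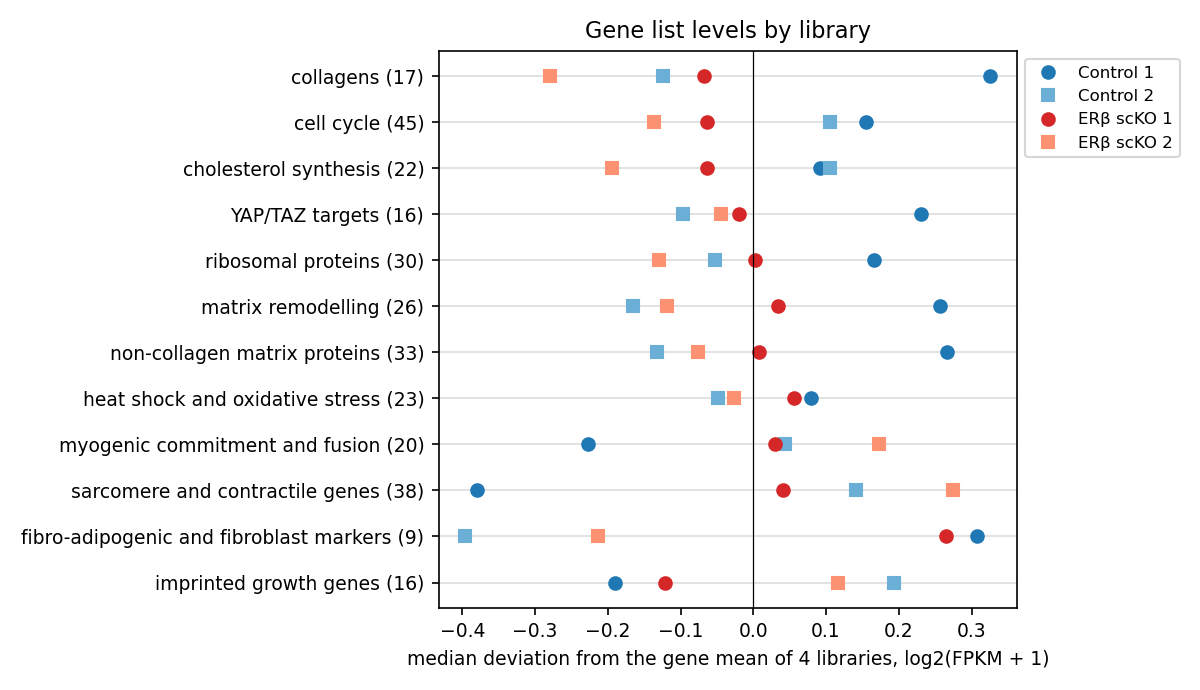
For each gene list (number of measured genes in brackets) the points give the median deviation of each library from the gene means of the 4 libraries, in log2(FPKM + 1). For the cell cycle both ERβ scKO libraries (−0.06 and −0.14) lie below both Control libraries (0.16 and 0.11), whereas for collagens Control replicate 1 stands at 0.33 and the other 3 libraries at −0.07 or lower, and for sarcomere genes Control replicate 1 stands at −0.38 and the other 3 libraries at 0.04 or higher.

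Ribosomal protein genes had a median of −0.14 (21 of 30 lower), −0.01 without Control replicate 1, −0.21 without Control replicate 2 and −0.07 without ERβ scKO replicate 2. Their median was −0.16 between the replicate 1 libraries and −0.06 between the replicate 2 libraries. Camera did not call the list (adjusted p = 0.0873) and called it lower with replicate number as a block (adjusted p = 0.0305), a call lost with the block and an estimated correlation (adjusted p = 0.967 with an estimated correlation). Rps2 had a log2 ratio of −0.23 and Rpl10 −0.14. Genes of heat shock and oxidative stress had a median of 0.07 (14 of 23 higher), 0.12 without Control replicate 1 and −0.05 without Control replicate 2. Without ERβ scKO replicate 1 their median was 0.04, between the replicate 1 libraries it was −0.01 and between the replicate 2 libraries 0.03. The chaperones Hspa8 and Hsp90aa1 had log2 ratios of −0.09 and 0.27. In all, 10 of the 31 lists with at least 5 measured genes had medians in the outer 5% of their random lists, 7 low and 3 high. Lists of unrelated genes would give 1.6 by chance. Members of a real list can move together, so more lists could lie outside without a difference of genotype. Within Control, replicates 1 and 2 deviated by −0.38 and 0.14 for sarcomere genes and by 0.33 and −0.12 for collagens. The other 21 lists had medians from −0.08 to 0.12, among them satellite cell identity (0.01), Notch and quiescence (−0.02), estrogen receptors and targets (−0.02), apoptosis (0.03), p53 targets and cell cycle inhibitors (0.04), interferon response (0.07) and oxidative phosphorylation (−0.03).

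Esr2, which encodes ERβ (chromosome 12, 76120419 to 76177259), was at 0.234 and 0.202 FPKM in the Control libraries and listed at 0 in both ERβ scKO libraries. At this gene's length 3 fragments correspond to 0.30 to 0.35 FPKM, so its level was below what this depth could measure in every library and its values do not check the labels. The authors did not test it. Esr1, which encodes ERα, was at 0.627 ± 0.240 FPKM in Control and 1.31 ± 0.450 in ERβ scKO, a difference larger than either SD in a gene that the authors did not test. Markers of satellite cells and myoblasts differed by less than the spread between replicates: Pax7 was at 10.6 ± 0.179 and 10.6 ± 0.251 FPKM, Myf5 at 15.2 ± 5.19 and 15.8 ± 3.39, and Myod1 at 350.1 ± 49.2 and 347 ± 28.8 in Control and ERβ scKO. The cell cycle inhibitor Cdkn1a was at 352 ± 50.4 FPKM in Control and 449.8 ± 35.2 in ERβ scKO, and limma did not call it (log2 ratio 0.36, SE 0.13, adjusted p = 0.837, higher in 2 of 2 ERβ scKO libraries than in either Control library). Xist, the transcript of the inactive X chromosome, was at 93.2 ± 24.5 and 107 ± 7.71 FPKM, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in all 4 libraries.

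The second question was which single genes differed. The authors' own test called 0 of 9426 tested genes at q under 0.05. The lowest q, 0.0589, was shared by 8 genes at the authors' p of 5e-05: Igfbp5 and Nptx1, higher in ERβ scKO, and Col1a1, Col6a3, Lars2, Nt5dc2, Rn45s and Rpl36, lower. These 8 were chosen after their values were seen. Igfbp5, which encodes a secreted protein that binds insulin-like growth factors (chromosome 1, 72858065 to 72874865), was at 28.9 ± 0.672 FPKM in Control and 57.9 ± 5.61 in ERβ scKO (log2 ratio 0.98). Limma did not call it over all genes (adjusted p = 0.299, 0.274 with replicate number as a block), and called it when adjusted over the list alone, as did the authors' p. Nptx1, a neuronal pentraxin (chromosome 11, 119538719 to 119547820), was at 6.57 ± 2.29 FPKM in Control and 14.2 ± 1.93 in ERβ scKO. Nt5dc2 (chromosome 14, 31134853 to 31168641) was at 57.0 ± 17.6 FPKM in Control and 29.9 ± 3.96 in ERβ scKO. Lars2, the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366940 to 123462664), was at 77.7 ± 21.8 and 32.8 ± 0.311 FPKM, and Rn45s, the precursor of ribosomal RNA (chromosome 17, 39842997 to 39848829), at 236 ± 32.1 and 66.3 ± 3.42 FPKM. Rpl36, a ribosomal protein gene (chromosome 17, 56613395 to 56614246), was at 702 FPKM in Control replicate 1 and between 188 and 262 FPKM in the other 3 libraries.

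**Figure D3:**
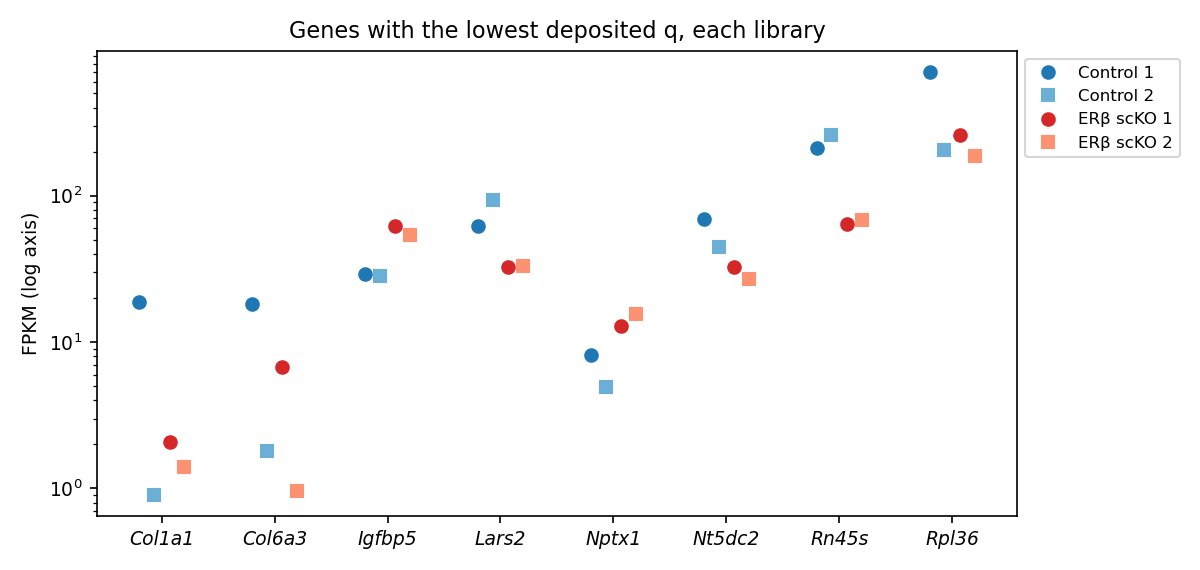
The FPKM of each library (log axis) is shown for the 8 genes that share the lowest deposited q, with circles for replicate 1 and squares for replicate 2. Igfbp5 and Nptx1 are higher in both ERβ scKO libraries than in both Control libraries, Lars2, Nt5dc2 and Rn45s are lower in both, and for Col1a1, Col6a3 and Rpl36 Control replicate 1 is the highest library.

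At the authors' unadjusted p under 0.05 there were 306 genes, where chance gives 471 of those tested; 125 were higher and 181 lower in ERβ scKO, and the second deposited sheet lists these same 306 by symbol and locus. In 129 of the 181 lower genes Control replicate 1 was more than 1.3 times as high as each of the other 3 libraries. The median GC content was 57.2% in the lower genes, 45.9% in the higher genes and 49.6% in all measured genes. The first principal component of the libraries, with 50.8% of the variance, placed Control replicate 1 at 34.5 and the others at −7.5 (Control replicate 2), −7.9 and −19.2 (ERβ scKO replicates 1 and 2).

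The limma fit on the 4 library values called 4 of 11201 genes at an adjusted p of 0.05, and 518 had an unadjusted p under 0.05, where chance gives 560. That number depended on the fit: it was 947 with replicate number as a block, 592 without Control replicate 1, 2276 without Control replicate 2, 235 without ERβ scKO replicate 1 and 149 without ERβ scKO replicate 2. Rn45s was lower in ERβ scKO (log2 ratio −1.81, SE 0.13, adjusted p = 0.03, both libraries below both Control libraries; 0.0144 with replicate number as a block). The other 3 were small nucleolar RNAs with annotated lengths of 90 to 184 bases, which were listed at 0 in both libraries of one group: Snora23 was at 10.2 and 9.11 FPKM in Control and at 0 in ERβ scKO, Snora31 at 0 in Control and at 191 and 374 FPKM in ERβ scKO, and Snord35a at 0 in Control and at 1740 and 1739 FPKM in ERβ scKO. The authors' own test did not call these 3: its p was 0.220, 0.0857 and 0.182 in that order, with a q of 0.998 for each. With the genes shorter than 300 bases left out limma called 0 genes, with a lowest adjusted p of 0.0825 and 528 genes at an unadjusted p under 0.05. With 1 library left out, which of the 4 genes were called depended on the library. Snora31 and Snord35a were called each time. The call of Rn45s was lost whichever ERβ scKO library was left out, and that of Snora23 whichever Control library was left out.

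Among markers of other cell types, those of fibro-adipogenic progenitors and fibroblasts differed more between replicate numbers than between groups. Their list had a median of 0.00 between the groups, but replicate 2 was lower than replicate 1 in Control (−0.83) and in ERβ scKO (−0.57). Of its 20 genes 9 were measured; Pdgfra, the receptor that marks fibro-adipogenic progenitors, was at 3.17 and 0.446 FPKM in Control and 2.64 and 0.149 in ERβ scKO. Pericyte and smooth muscle markers had a median of −0.05, and 1 of them, Pdgfrb, was called lower with the authors' p adjusted over the list alone; it was at 8.28 and 2.84 FPKM in Control and 4.06 and 1.45 in ERβ scKO (the authors' q over all genes 0.492), and was chosen after its values were seen. Schwann and neural markers had a median of −0.04 between the groups. Of immune, endothelial and adipocyte markers 3, 3 and 4 genes were measured, and of erythroid markers 0. Lyz2 and Ctss, abundant in macrophages, were listed at 0 in all 4 libraries.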

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

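The set tests, the values for the libraries of each replicate number, the list medians with 1 library left out, the removal of short genes and of the GC trend, and the unadjusted thresholds were chosen after the data were seen; the other alternatives were planned. The median of the cell cycle list stayed outside its random lists in all 16 alternatives run, at −0.19 to −0.30 with 1 library left out. That of cholesterol synthesis stayed outside in 15 of 16 (−0.155 to −0.283 with 1 library left out), and was −0.134 between the replicate 1 libraries, inside the range. Of these 16, centring on the median moves a list and its random lists alike, so it could not change a percentile. Upper quartile scaling is nearly such a shift. With a pseudocount of 0.1, the log2 ratios of 2 of the 28 genes named by the rule, Esr2 and Esr1, moved by more than the combined replicate SD. The sign of a ratio of group means cannot change with the pseudocount.

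The authors' calls numbered 0 at q under 0.05. They stayed 0 with p adjusted again over genes with a mean of at least 1 or at least 5 FPKM. A q threshold of 0.01 and subsets of the called genes could only give 0. There were 8 calls at q under 0.1 (2 higher, 6 lower) and 306 at an unadjusted p under 0.05 (125 higher). List members called were 3 at q under 0.1 and 21 with the authors' p adjusted over the list alone. Lists outside the limits numbered 10, 3 by list means and 5 between the replicate 2 libraries, and 7 to 14 with 1 library left out; of the 10, 5 stayed outside without Control replicate 1, 9 without Control replicate 2, 8 without ERβ scKO replicate 1 and 5 without ERβ scKO replicate 2. By list means the sarcomere value was 0.239 and inside the range.

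Limma's calls numbered 4, and none of these 4 genes entered the fit with the GC trend removed. Rn45s has no GC value, and the other 3 are shorter than 300 bases. The calls numbered 2 with no filter, 0 without short genes, 0 with the GC trend removed and 518 at an unadjusted p under 0.05. With replicate number as a block they numbered 6, and 1 with the GC trend removed and the block; leaving out 1 library gave 7 to 11. Profiles of the same replicate number correlated at 0.21 after the group means were removed, which with 2 libraries per group is 1 value for both numbers and does not settle whether the numbers pair the libraries, so the block is an alternative. The cause of these changes was not tested.

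Without Control replicate 1 the collagen median was 0.06, the reverse direction, and with 1 library left out it ranged from −0.552 to 0.06; between the replicate 2 libraries it was −0.061. The sarcomere median ranged from 0.039 to 0.563. The reversed medians of other lists were, without Control replicate 1, 0.137 for non-collagen matrix, 0.177 for matrix remodelling and 0.045 for YAP/TAZ targets (lowest values −0.242, −0.333 and −0.283 with another library left out); between the replicate 2 libraries 0.043, 0.096 and 0.074; 0.007 for matrix remodelling with the GC trend removed, where YAP/TAZ targets were at −0.057; and for heat shock −0.012 between the replicate 1 libraries and −0.051 to 0.119 with 1 library left out.

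Camera's calls numbered 4, 5 with the replicate block, 0 with an estimated correlation with or without the replicate block, 7 with the GC trend removed and the block, 0 by fry with or without the block, and 2 to 7 with 1 library left out. Adjusted p values with an estimated correlation were 0.872 for cell cycle and cholesterol synthesis and 0.975 for collagens and sarcomere, and 0.967 for all 4 with the block. By fry they were 0.343, 0.444, 0.994 and 0.994 in that order, and 0.666, 0.666, 0.778 and 0.709 with the block. With the GC trend removed the collagen value was 0.133. With 1 library left out they ranged from 2.89e-08 to 0.00132 for cell cycle, 1.95e-05 to 0.0474 for cholesterol synthesis, 0.000201 to 0.887 for collagens and 1.85e-09 to 0.7 for sarcomere. Depth limits low genes: Esr2 had a log2 ratio of −0.28 with a pseudocount of 1 and −1.67 with 0.1, from about 2 fragments in each Control library, and Esr1 0.51 and 0.96.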

Other observations

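The tests named below of Control replicate 1 alone, of fibroblasts, of myogenic differentiation and of short genes were chosen after the result was seen; those of the GC trend and of sequence shared with Rn45s were also added after the data were seen, but before their own results were known. Genes that p53 is known to activate went both ways. The list of 25 measured p53 targets and cell cycle inhibitors did not lie outside its random lists (median 0.04, 14 higher and 11 lower in ERβ scKO). Camera did not call it (adjusted p = 0.55). It also holds Trp53 itself and cell cycle inhibitors that are not p53 targets, of which Cdkn2a, Cdkn2b and Cdkn2c were lower. Its split is therefore not one of p53 targets alone. Limma's unadjusted p was under 0.05 for 5 higher members and 1 lower member. The p53 target Cdkn1a was higher (log2 ratio of group means 0.35). Mdm2, the ubiquitin ligase that limits p53, was at 113 ± 3.78 FPKM in Control and 163 ± 10.2 in ERβ scKO (n = 2 each), Trp53inp1 at 18.5 ± 5.04 and 32.2 ± 1.84, Btg2 at 15.3 ± 0.862 and 21.4 ± 1.45, and the apoptosis gene Pmaip1 at 29.6 ± 3.77 and 46.2 ± 7.21. Lower in ERβ scKO on average were the p53 targets Gdf15 (log2 ratio −0.97, but −2.20 between the replicate 1 libraries and 0.60 between the replicate 2 libraries), Bbc3 (−0.48) and Bax (−0.23). Trp53inp1 and Pmaip1 passed with the authors' p adjusted over the list alone. None of the 7 genes from Mdm2 to Bax passed over all genes, and the authors did not test Gdf15. The nuclear RNAs Malat1 (89.2 ± 36.4 and 154 ± 17.4 FPKM) and Neat1 (85.3 ± 7.83 and 136 ± 10.1), often read as signs of RNA quality or of the nuclear share of RNA, had higher values in both ERβ scKO libraries than in either Control library, as did Hist1h2bc (15.3 ± 2.43 and 30.1 ± 3.22), a histone gene with polyadenylated transcripts. All 3 passed with the authors' p adjusted over the list alone, and none over all genes. Limma adjusted over the list alone called 3 of the 4 measured genes of the RNA quality list, 2 higher and 1 lower in ERβ scKO. The lower one, Rmrp, was at 3.21 and 2.82 FPKM in Control and listed at 0 in ERβ scKO. It is a short gene (chromosome 4, 43492785 to 43493059) that the authors did not test, and the fragments behind its low values are not known. These genes were chosen after their values were seen.

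Some genes followed replicate number in both groups. The cytokines Ccl2 and Ccl7 were at 9.74 and 8.69 FPKM in Control replicate 1 and at 8.50 and 11.3 in ERβ scKO replicate 1, and both were between 0.997 and 1.98 in the replicate 2 libraries. Imprinted growth genes were higher in replicate 2 than in replicate 1, with list medians of 0.35 in Control and 0.24 in ERβ scKO; Igf2 was at 119.7 and 160.2 FPKM in the replicate 1 libraries of Control and ERβ scKO and at 225 and 249 in the replicate 2 libraries. The labels give each replicate number a further number, the same in both groups, whose meaning is not stated.

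The lower values of cell cycle genes in ERβ scKO did not rest on Control replicate 1: without it the median was −0.23, at the 0.0 percentile of its random lists. The difference of ERβ scKO from Control followed GC content (Spearman correlation of −0.34 across genes, which are not independent) between the replicate 1 libraries (−0.44) and not between the replicate 2 libraries (−0.02), with −0.51 for replicate 2 over replicate 1 in Control and −0.14 in ERβ scKO, but with that trend removed the median was −0.26, still at the 0.0 percentile, which argues against the trend as the whole cause. Further myogenic differentiation in ERβ scKO, in which cells leave the cycle, cannot be told apart from a difference in cycling itself: the sarcomere median was above 0 in 3 of the 4 pairs of an ERβ scKO with a Control library and −0.064 in the pair of ERβ scKO replicate 1 with Control replicate 2, where the cell cycle median was −0.18. Whether fewer cells were cycling was not tested, and Mki67 did not go one way (log2 ratio 0.40 between the replicate 1 libraries and −0.44 between the replicate 2 libraries); a difference in RNA quality, which the higher Malat1 and Neat1 leave open, and one between cell preparations unrelated to the genotype were not tested either.

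The lower values of collagen genes in ERβ scKO disappeared without Control replicate 1, where the median was 0.06, at the 83.52 percentile of its random lists. The GC trend does not account for them as a whole, since with it removed the median went from −0.40 (quartiles −0.65 and −0.12) to −0.35 (−0.41 and 0.03), at the 0.0 percentile; camera's call ended (adjusted p = 0.133), with 12 of 17 collagens lower in place of 15. More fibroblasts in Control replicate 1 may have contributed and cannot be told apart from other differences of that library: fibroblast markers differed by −0.01 between the replicate 1 libraries, where the collagens differed by −0.42, but only 3 of these markers reached 5 FPKM. A difference of the genotype in collagen genes was not excluded. Between the replicate 2 libraries the median was −0.06, with 10 of 17 lower, but inside the range of its random lists (percentile 15.94). Col6a3 (−0.51) and Col12a1 (−0.51) were among the lower genes, while Col1a1 was higher in that pair.

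Limma called Rn45s and 3 small nucleolar RNAs, and Rn45s and Lars2 were among the 8 genes that shared the authors' lowest q. Of the 3 called genes shorter than 300 bases, 0 had a value above 0 in all 4 libraries, as few fragments on very short genes would give, but the number of fragments behind them is not known (a conversion by annotated length would give 460 for Snord35a in ERβ scKO replicate 2), so this cannot be told apart from a difference in these RNAs. Ribosomal RNA carried over in different amounts could account for Rn45s, and for Lars2 if the gene held sequence like ribosomal RNA, but Lars2 shared 0 stretches of 31 bases with the transcripts annotated inside the Rn45s locus. That bound had been set in advance to exclude the explanation and was wrong: no ribosomal RNA annotated in the reference is longer than 1849 bases and the locus has 5833, so the longer large-subunit RNA was not searched as a whole, which was seen only after the result. The 16 other mitochondrial tRNA synthetases had a median log2 ratio of −0.13 (−0.57 to 0.16), against −1.22 for Lars2.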
